A study of Mus musculus with 8 samples.

How the data were processed

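The count matrices as deposited hold UMI counts per gene and cell barcode, which the authors made from the reads with Cell Ranger before deposition; no normalised values were used. Per the submitters' processing notes the tools were Cell Ranger 3.1.0 and STAR, with the mouse build mm10. Per the file headers the P120 matrices came from version 6.0.0 of the Cell Ranger software with 32285 features and the P420 matrices from version 3.0.2 with 28692 features. The P75 headers named no version, also with 28692 features. The notes do not say how barcodes were called as cells. The lowest deposited barcode held 969 UMIs in the wild type and 1835 in the knockout library, and between 500 and 503 at P120 and P420. The P75 libraries were thus compared above unlike limits. Per the labels the mice were C57BL6/J, the forebrain was dissociated, and CD11b-positive cells were retained on a magnetic column. The labels do not say whether the libraries are separate animals, nor how many mice went into each. The P420 descriptions speak of global Bace1 deletion while the genotypes read Bace1-fl/fl, so these libraries are named here by genotype.

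Barcodes with fewer than 500 detected genes or more than 10% mitochondrial UMIs were left out. In the order of the depths in the report, 17, 2, 196, 254, 244, 282, 954 and 250 barcodes fell under the former limit and 53, 59, 302, 462, 298, 499, 1218 and 467 over the latter. Doublet scores came from the Scrublet method in scanpy, per library. Its automatic threshold called almost none, so the highest-scoring barcodes were removed by rank, at 0.8% of barcodes per 1000 barcodes. That came to 5.12% and 5.05% at P75, 3.54%, 4.34%, 5.40% and 4.12% at P120 and 6.62% and 6.47% at P420. Libraries of 1 age were clustered jointly, without batch correction: counts scaled to an equal total per cell and log-transformed, 2000 variable genes, 30 principal components, 20 nearest neighbours with shared-neighbour weights, and Leiden clustering at resolution 1.0 with random seed 1. Clusters were named from 17 marker sets for brain, vessel and blood cells. A name needed a marker score of at least 0.35, at least 3 markers each detected in 10% of the cells, and no other class that had at least as many markers (and any at all) among the 10 leading genes of the cluster. Shallow clusters with no marker of their own among those 10 were also left unnamed. Rank removal of doublets and these naming rules were set after seeing the data.

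UMIs were summed over the microglia-like cells of each library and scaled to CPM. A comparison gives log2 of the ratio of CPM + 1. Genes counted as measured at a mean of at least 20 CPM over both libraries, and counts of higher or lower genes take those at 1.5-fold or more. Exact Poisson intervals were put on each sum and exact conditional binomial intervals on each ratio, at 95%. Depth ran from 19066705 UMIs (wild type at P75) to 92352826 (5xFAD at P420) per library, and the 8 totals stand in the results. At that depth the intervals of named log2 ratios reached medians between 0.045 and 0.093 to either side. For a gene with 0 counts in a library a floor of 3 counts over its summed cells was used. No ratio was taken between libraries of different ages, because age goes with the annotation, the processing version and, for P75, the sex-linked genes. CPM of a few genes are given for all 8 libraries, and the closing part sets P75 values beside the range of the other ages with that limit. edgeR was used for its TMM factors alone, and no model was fitted.

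The 18 gene lists, fixed with the cell type markers, were homeostatic microglia, DAM stage 1, DAM stage 2, interferon response, MHC class I, MHC class II, cytokines and chemokines, immediate early and dissociation stress, lysosome, lipid transport and sterol, phagocytosis receptors and complement, amyloid precursor protein processing and secretases, glycolysis, nuclear oxidative phosphorylation, mitochondrially encoded, proliferation, TGF-beta signalling and transcription factors, and sex-linked genes. Some genes stand in more than 1 list. Each list was described by the median log2 ratio of its measured members less that of all measured genes, with an interval from 200 Poisson draws. Its percentile came from 10000 random lists of the same size, matched in 20 bins of expression.

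Named genes followed a rule. Per comparison they were the 10 highest and 10 lowest ratios past 1.5-fold among measured genes, leaving out ribosomal protein, mitochondrially encoded and haemoglobin genes and models named only Gm or Rik. To these were added Bace1 in every library and, per list, up to 4 measured members with the largest ratios in either direction. A few of the genes so named are not reported here. A gene outside this rule is said in the text to have been chosen after its values were seen. Gene positions are those of GRCm38/mm10.

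For the stage 2 share every microglia-like cell was thinned to 1000 UMIs, and cells with fewer were left out. The limit was the 95th percentile of the reference library of the same age: wild type at P75, no 5xFAD and no tamoxifen at P120, and no 5xFAD at P420. Because scores come in steps of 1 UMI, the reference share can lie below 5%. Detection shares used the same thinned cells, with endothelial cell-like cells as the measure of free RNA. Correlations across genes joined comparisons with no library in common.

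The comparisons, gene lists, markers, thresholds, rule for named genes and most of the alternatives were chosen before the data were examined. The alternatives covered the cells summed, the detected gene minimum, called doublets, scaling (TMM and median-of-ratios), genes in the total, weight per cell, CPM minimum, fold threshold, pseudocount, clustering resolution, and the limit, thinning and members of the stage 2 score. The ratios, their intervals and the list percentiles were run on Poisson counts simulated from the summed counts, with 200 changed genes per comparison. This recovered 100% of 2-fold changes in both directions, called 0 unchanged genes, and between 94.71% and 95.49% of intervals held the true ratio. The simulation held counting error alone, with no spread between animals, so it checks the arithmetic only. Filtering, doublet removal, clustering, naming, thinning and the matched checks were not simulated. Of 40 random lists per comparison, 0 to 2 fell outside the central 95%. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.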

Results

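CD11b-positive cells were drawn from the forebrain of C57BL6/J mice with magnetic beads, and their transcripts were counted by droplet 3' single-cell RNA sequencing. The series held 8 libraries in 8 groups, 1 library per group, at 3 ages. At P75 a wild type library stood beside a Bace1 knockout library. Bace1 encodes the beta-secretase that makes the initial cleavage of the amyloid precursor protein. At P120 all 4 libraries came from mice with floxed Bace1 and Cx3cr1-CreER, a Cre recombinase made active by tamoxifen in cells that express Cx3cr1. These 4 crossed tamoxifen (5 doses of 100 mg/kg, or none) with 5xFAD, a transgenic model of amyloid deposition. At P420 a Bace1-fl/fl library stood beside a Bace1-fl/fl 5xFAD library, and the labels gave neither a Cre nor tamoxifen for either one. The series was made to ask how loss of Bace1 bears on the passage of microglia from the homeostatic state towards disease-associated microglia (DAM), whose stage 1 and stage 2 genes formed a pair of the lists examined here.

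At P75 the wild type library held 6406 barcodes with 19066705 UMIs (median 2616 per barcode) and the knockout library 6311 barcodes with 24903547 UMIs (median 2903 per barcode). The P120 libraries without 5xFAD held 4430 barcodes with 54283060 UMIs (median 7652 per barcode) without tamoxifen and 5432 barcodes with 61096458 UMIs (median 6791 per barcode) with it. Those with 5xFAD held 6745 barcodes with 83912172 UMIs (median 9282 per barcode) without tamoxifen and 5145 barcodes with 75714123 UMIs (median 9717 per barcode) with it. At P420 the library without 5xFAD held 8287 barcodes with 45995245 UMIs (median 4878 per barcode) and the 5xFAD library 8094 barcodes with 92352826 UMIs (median 9074 per barcode). With 1 library per group, the spread between animals was not estimated and no difference between groups was tested, so every comparison describes these libraries alone. An additive fit over the P120 libraries was not made, since it would take unlike differences between the tamoxifen libraries with and without 5xFAD, which are described here, for spread. A fit of 5xFAD over its 3 pairs of libraries, blocked by pair, would leave 2 residual degrees of freedom. It was not made either, because the pairs differ in age, tamoxifen and Cre label, and each pair is described by itself. The 95% intervals are exact Poisson or binomial intervals, or come from Poisson draws for a list median, and cover counting error only.

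Microglia-like cells made up most of every library. Their share of the cells left after filtering was 87.2% (86.4 to 88.1) in the wild type library and 88.8% (88.0 to 89.6) in the knockout library. It was 80.7% and 75.6% at P120 without and with tamoxifen, 90.5% and 83.8% in the matching 5xFAD libraries, and 67.0% and 85.5% at P420 without and with 5xFAD. Border macrophage-like cells, the macrophages of meninges and vessels, made up 2.81% and 3.91% at P75. At P120 they made up 3.70% without and 5.05% with tamoxifen, 1.71% and 2.90% in the same order with 5xFAD, and at P420 3.34% and 1.39% without and with 5xFAD. Endothelial cell-like shares were 3.06% and 1.64% at P75, 1.56%, 3.23%, 0.772% and 3.83% at P120, and 3.70% and 1.42% at P420, in the order of the depths above. Neutrophil-like cells made up 0.731% of the wild type library and 0.084% of the knockout library, and 1.36% and 0.329% at P420 without and with 5xFAD. T cell-like cells were 0.447% and B cell-like cells 0.255% at P420 without 5xFAD, against 1.60% and 0.587% with it. Because the cells had been selected for CD11b, these shares describe the selected suspension and not the brain.

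Clusters that met no naming rule were kept out of every class. They held 3.74% of the wild type and 3.74% of the knockout cells, 12.3%, 13.6%, 6.48% and 6.91% of the P120 libraries in the order above, and 22.4% and 4.28% at P420. Libraries of 1 age were clustered together, and within the microglia-like class most cells of each library lay in a few clusters. Clusters 0 and 5 held most of the wild type cells and clusters 1 and 2 most of the knockout cells. At P120 clusters 0 and 4 held most cells without tamoxifen and clusters 0 and 2 most with it, while clusters 1, 3 and 5 held most cells of both 5xFAD libraries. At P420 cluster 0 held most cells without 5xFAD and clusters 1, 2 and 3 most with it. A cluster filled mainly by 1 library can reflect that library and not a cell type. At Leiden resolutions of 0.5 and 1.5 the wild type microglia-like share was 48.3% and 58.6%, since large wild type clusters were then left unnamed. Comparisons below use UMIs summed over the microglia-like cells, which numbered 5250 and 5271 at P75, 3161, 3529, 5394 and 3675 at P120 and 4194 and 5973 at P420.

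Bace1 (ENSMUSG00000032086, chromosome 9, 45838580 to 45864399 in GRCm38/mm10) was counted at low levels in the microglia-like cells of every library, those labelled knockout or tamoxifen included. It was at 9.37 (7.86 to 11.1) CPM, that is, UMIs scaled to an equal total per library, in the wild type library and 10.4 (8.99 to 11.9) in the knockout library. At P120 it was at 16.4 (15.2 to 17.6) CPM without and 15.3 (14.2 to 16.5) with tamoxifen, and in the 5xFAD libraries at 9.17 (8.48 to 9.90) and 7.37 (6.71 to 8.08). At P420 it was at 13.01 (11.7 to 14.4) CPM without and 5.95 (5.39 to 6.55) with 5xFAD. The tags come from the 3' end of the transcript and the labels do not say which part of the gene was removed, so these counts check neither the knockout nor the recombination. In endothelial cell-like cells Bace1 was at 8.63 CPM in the wild type library and between 18.4 and 38.6 in the other 7, so RNA of other cells was not excluded as a source either. Cx3cr1 (chromosome 9, 119901616 to 120069879), the fractalkine receptor gene into which CreER is commonly inserted, was at 1823, 1812 and 1855 CPM in 3 of the P120 libraries. It was at 3057 CPM in the P120 5xFAD library without tamoxifen. Cx3cr1 was at 3111 and 3693 CPM in the wild type and knockout libraries, and at 3483 and 1852 at P420 without and with 5xFAD. The sex-linked list also set the ages apart: Xist, the RNA that silences an X chromosome, was at 0.625 and 0.104 CPM at P75 and between 1175 and 2063 CPM in the other 6 libraries, while the Y-linked Ddx3y was at 92.0 and 91.1 CPM at P75 and at most 0.0140 elsewhere. Within each comparison the libraries had the same pattern.

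**Figure D1:**
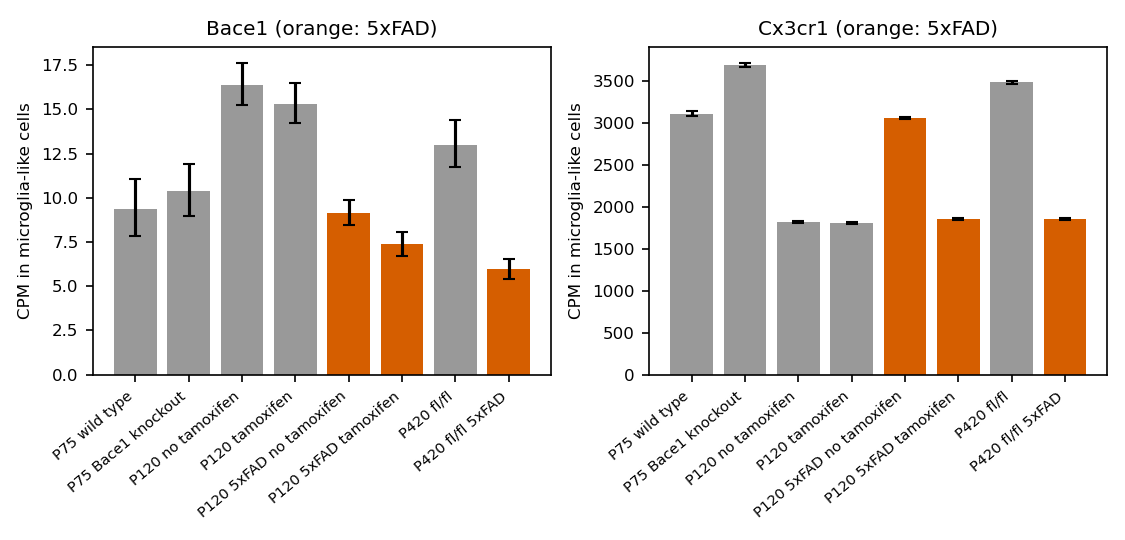
CPM of Bace1 and of Cx3cr1 in the microglia-like cells of the 8 libraries, 1 bar per library, with exact 95% Poisson intervals. Bace1 lies between 5.95 and 16.4 CPM, and Cx3cr1 in the P120 5xFAD library without tamoxifen lies at 3057 CPM against 1855 with tamoxifen.

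Ratios between libraries are log2 ratios of CPM + 1. Each is given as its distance from the median of all measured genes of its comparison, called the relative log2 ratio. Single gene ratios under an alternative setting or in border macrophage-like cells were not centred in this way. A gene counted as measured where the mean CPM of both libraries reached 20. A gene below 20 CPM in 1 library was thus measured only where higher in the other, so this rule fixed its direction. Counts of genes refer to those at least 1.5-fold apart, in CPM for all measured genes unless stated and relative to the median for members of a list, where the count in CPM is given if it differs, while beside the values of a single gene higher and lower give the direction alone. The median of all measured genes lay at 0.02 for the knockout comparison, -0.04 and 0.08 for tamoxifen without and with 5xFAD, -0.48 and -0.35 for 5xFAD without and with tamoxifen, and -0.42 for 5xFAD at P420. Counts are shares of a total, so a median below 0 was not separated into a fall of many genes or a rise of a few abundant ones. Trimmed mean of M-values (TMM) scaling, also used below, centres most genes near 0 by construction. Percentiles of list medians among random lists of matched expression are a description of these libraries. Sex-linked genes, of which 2 were measured, had relative medians of -0.05 for knockout, 0.08 and -0.15 for tamoxifen, -0.07 and -0.31 for 5xFAD at P120 and -0.73 at P420.

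The knockout comparison at P75 asked what differed in microglia-like cells of the library labelled Bace1 knockout. A small set of genes stood far apart, while the homeostatic and DAM lists as groups lay close to the median of all genes. Spint1, a membrane-bound inhibitor of serine proteases, was at 55.8 CPM (95% interval 52.5 to 59.2) in the knockout library and at 0.139 (0.0168 to 0.501, 2 UMIs) in the wild type library. In the 6 libraries of the other ages it lay between 73.4 and 129 CPM, nearer to the knockout than to the wild type value. The transcription factor Ets1 was at 38.7 against 2.85 CPM and Lrba, a protein of vesicle traffic, at 170.4 against 20.9 CPM. Relative log2 ratios were 1.48 for Fcrl1, 1.42 for Hist3h2a, 1.34 for Cd84, 1.34 for Ang and 1.31 for Bbs9, of which Cd84 encodes a SLAM family receptor and Ang the ribonuclease angiogenin. Lower in the knockout library were the myelin gene Mbp (-1.21) and the prostaglandin D synthase Ptgds (-1.75), transcripts of other brain cells that free RNA can carry into droplets. The choroid plexus transcript Ttr, chosen after its values were seen, went the other way, at 642 against 280.1 CPM in microglia-like and 699 against 236 in endothelial cell-like cells. After thinning it was found in 47.1% of knockout and 25.2% of wild type microglia-like cells. The other lowest genes had relative log2 ratios of -1.66 for Sfi1, -1.57 for Rcan2, -1.33 for Cdk5rap1, -1.18 for Cwc22, -1.16 for Rab34, -1.12 for Nccrp1 and -1.11 for Trp53i11. Of 5829 measured genes, 72 were at least 1.5-fold higher and 88 lower, or 68 and 98 relative to the median.

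The homeostatic list, genes that mark resting microglia, had a relative median of 0.05 (95% interval 0.04 to 0.07) in the knockout comparison, and 1 of its 24 measured genes was at least 1.5-fold apart. That gene was Fcrls, an Fc receptor-like gene of microglia, at 1574 against 683 CPM. In the libraries of the other ages Fcrls lay between 1661 and 2032 CPM, nearer to the knockout than to the wild type value. The DAM stage 1 list lay at 0.09 (95% interval 0.05 to 0.12) and the stage 2 list at 0.02 (95% interval -0.01 to 0.08). Apoe, the main apolipoprotein of the brain and a stage 1 gene, was lower in the knockout library at 1295 against 2555 CPM and the 1 stage 1 gene past 1.5-fold, which the lysozyme gene Lyz2, at 232 against 311 CPM, did not reach. Of the stage 2 members 2 of 14 were at least 1.5-fold higher, the cathepsin gene Ctsl at 628 against 307 CPM and the osteopontin gene Spp1 at 48.5 against 30.3 CPM, while Serpine2, at 545 against 369.9 CPM, fell short. Spp1 was lower (-0.06) when each cell weighed the same, and after thinning 0.531% of knockout cells held a Spp1 UMI against 1.03% of wild type cells. Among random lists the percentiles were 98.1 for homeostatic, 98.0 for stage 1 and 72.9 for stage 2 genes. The MHC class II list, for antigen presentation to T cells, had a median of -0.45 (95% interval -0.50 to -0.37), at percentile 0.01. H2-Eb1 (-0.66), H2-Aa (-0.60) and the invariant chain gene Cd74 (-0.59) were lower, while H2-DMa, a peptide loading factor, was higher (1.13). After thinning, H2-Aa was found in 2.30% of knockout and 4.43% of wild type cells. Endothelial cell-like cells had 4.12% (1.14 to 10.2) and 3.28% (1.21 to 6.999), so free RNA was not excluded as the source of these counts, as for Cd74 below. Interferon response genes lay at 0.42 (95% interval 0.25 to 0.48) over 5 measured genes, among them Bst2 (0.47), and at 0.14 over all barcodes, and 0 of the 5 passed 1.5-fold. MHC class I lay at 0.15 with H2-T23 at 0.36, and lysosome genes at 0.15 with Ctsh at 0.44.

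The mitochondrially encoded list lay at -0.33 and the proliferation list at -0.37 in the same comparison, with mt-Atp8 at 47.0 against 101 CPM and the tubulin regulator Stmn1 at 79.7 against 114 CPM. The mitochondrially encoded median was -0.10 over all barcodes, and that of proliferation -1.04 with the coarser clustering and -0.22 when each cell weighed the same. Nuclear genes of oxidative phosphorylation lay at -0.08 and glycolysis at 0.03, but at 0.06 over all barcodes and -0.06 with the coarser clustering in that order. Genes of lipid transport and sterol synthesis lay at -0.17 and cytokines and chemokines at -0.14, the latter at 0.07 over all barcodes. Il1a lay at -0.61 and the chemokine gene Ccl3 at 0.40. The immediate early and stress list was at 0.00 with members on both sides, such as Egr1 at 0.97 and the heat shock gene Hspa1a at -0.69, and at -0.50 with the coarser and -0.36 with the finer clustering. Phagocytosis receptors and complement lay at -0.01, genes of amyloid precursor protein processing at 0.01 with App at 0.33, and TGF-beta signalling and transcription factors at 0.05 with Bhlhe41 at -0.71. Of the 85 named genes, 83 had at least 100 UMIs in both libraries, and the intervals of their log2 ratios reached a median of 0.093 to either side. With microglia-like cells taken from the coarser clustering, where 41.7% of wild type cells were unnamed, the stage 1 median was -0.04, the stage 2 median -0.06 and the MHC class II median -0.80. The homeostatic median was 0.10 over all barcodes and the stage 2 median 0.09 when each cell weighed the same.

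Tamoxifen without 5xFAD at P120 set a floxed Bace1 library with Cx3cr1-CreER given tamoxifen beside one given none. The libraries with and without tamoxifen were nearly alike: 7 of 6493 measured genes were at least 1.5-fold higher and 2 lower. Linker and core histone genes were among the higher ones, with Hist1h2ac at 45.0 against 17.1 CPM, Hist1h1d at 105 against 52.6 CPM and Hist1h1e at 235 against 139.8 CPM. Hcar2, a receptor for ketone bodies and niacin, was at 43.4 against 22.8 CPM, the interferon-induced chemokine gene Cxcl10 at 26.7 against 16.7 CPM and Tcim at 41.4 against 27.1 CPM. The lower genes were the lysosomal arylsulfatase gene Arsb at 287 against 687 CPM and Hspa1a at 35.8 against 56.8 CPM. Over all barcodes, 74 genes higher and 10 lower passed the same threshold.

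No member of the homeostatic, stage 1 or stage 2 lists was 1.5-fold apart in that comparison. The homeostatic median was -0.02 (95% interval -0.03 to -0.01), or -0.05 over all barcodes, with P2ry12 at -0.18 and Sall1 at -0.16. The stage 1 median was 0.15 (95% interval 0.13 to 0.17) with Lyz2 at 0.33 and Apoe at 0.27, and the stage 2 median 0.09 (95% interval 0.05 to 0.10) with Cd52 at 0.50 and the lipoprotein lipase gene Lpl at -0.42. MHC class II lay at 0.34 (95% interval 0.26 to 0.40) over 3 measured genes, with Cd74 at 57.5 against 40.8 CPM, but at -0.09 over all barcodes and at 0.01 with the unnamed clusters nearest microglia added. The interferon list lay at 0.12, MHC class I at 0.12, and cytokines and chemokines at -0.12 with Ccl4 at -0.39, or at 0.01 over all barcodes. Oxidative phosphorylation lay at 0.16, mitochondrially encoded genes at 0.16, glycolysis at 0.10 and the immediate early list at 0.14 with Jun at 0.43. Medians of the other lists lay between -0.04 (TGF-beta signalling and transcription factors) and 0.09 (lysosome). Intervals of the 72 named ratios reached a median of 0.045 to either side.

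Tamoxifen with 5xFAD at P120 was the same comparison between 5xFAD libraries. The medians of the antigen presentation and DAM lists lay below that of all genes and the homeostatic median above it, though few members of most of these lists were 1.5-fold apart. The MHC class II genes H2-Eb1, H2-Aa and H2-Ab1 were at 36.3 against 119, 59.0 against 176 and 84.3 against 202 CPM with against without tamoxifen, and Cd74 at 338 against 774. The glycoprotein gene Gpnmb was at 30.8 against 98.4 CPM and Spp1 at 168 against 449 CPM. Mamdc2 (-1.39), the galectin gene Lgals1 (-1.36), the Wnt antagonist gene Dkk2 (-1.29) and the transcript AY036118 (-1.71) were also among the lowest. AY036118 was lower in other cells of that library too, at 1685 against 4516 CPM in border macrophage-like and 960.5 against 2297 in endothelial cell-like cells. Higher in the tamoxifen library were Cdkn1a, which encodes a cell cycle inhibitor, at 169 against 63.1 CPM and Ddit4, a stress-induced inhibitor of mTOR signalling, at 44.8 against 17.4 CPM. Fkbp5 at 124 against 57.5 CPM and Tsc22d3 at 115 against 56.6 CPM are genes induced by glucocorticoids. Il7r (0.96), Ecscr (0.94), Grap (0.94), Serpinf1 (0.90) and Chst1 (0.86) followed. Ttr, the choroid plexus carrier of thyroid hormone, had the highest ratio at 49.2 against 2.42 CPM, and 5.59% of microglia-like cells with tamoxifen had a Ttr UMI after thinning against 5.99% of endothelial cell-like cells, which is the level of free RNA. Of 5688 measured genes, 45 were at least 1.5-fold higher and 43 lower, 32 and 56 relative to the median, and 31 higher and 61 lower with TMM scaling. Over all barcodes 134 higher and 42 lower genes passed the threshold.

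The MHC class II median was -1.30 (95% interval -1.32 to -1.27) with 4 of 6 measured genes at least 1.5-fold lower, and -0.72 over all barcodes or -0.75 with the unnamed clusters nearest microglia added. MHC class I lay at -0.38 (95% interval -0.41 to -0.35), with 1 of 9 at least 1.5-fold lower, H2-Q7 at 55.4 against 121 CPM and H2-K1 at 819.6 against 1161 CPM. The interferon list lay at -0.45 (95% interval -0.48 to -0.43) with 5 of 17 at least 1.5-fold lower relative to the median and 3 in CPM, among them Ifit2 (-1.11), Ifit3 (-0.87), Ifi204 (-0.71) and Oasl2 (-0.62). DAM stage 1 genes lay at -0.24 (95% interval -0.25 to -0.24), 1 of 10 at least 1.5-fold lower, with Apoe at 16670 against 28260 CPM, H2-D1 at -0.56 and B2m at -0.43. Stage 2 genes lay at -0.29 (95% interval -0.30 to -0.28), 3 of 21 at least 1.5-fold lower, with Lpl at 344 against 641 CPM and Hif1a at -0.56. The homeostatic list lay at 0.20 (95% interval 0.18 to 0.21), or 0.09 over all barcodes. Of its 24 genes 1 was at least 1.5-fold higher, the leukotriene synthase gene Ltc4s (0.79), and 1 lower, Cx3cr1 at 1855 against 3057 CPM, relative to the median. Tmem119 (0.52) and Selplg (0.41) did not pass on that scale, while in CPM 2 genes of the list were higher and 1 lower. Lipid transport and sterol genes lay at -0.22, among them the fatty acid binding protein gene Fabp5 (-0.86) and the oxysterol-forming enzyme gene Ch25h (-0.61). Proliferation genes lay at 0.46 (95% interval 0.40 to 0.50), with Top2a at 42.5 against 23.3 CPM and Mki67 at 37.0 against 22.0 CPM.

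Cytokines and chemokines lay at 0.19, with Il1b at -0.76, Tnf at 0.53 and Ccl2 at 0.50. The immediate early and stress list lay at 0.16, with Klf2 at 0.76 and Hspa1a at -0.93, and at -0.01 when each cell weighed the same. Medians were -0.13 for lysosome, -0.12 for mitochondrially encoded genes (or 0.00 over all barcodes), -0.10 for glycolysis, -0.05 for phagocytosis receptors and complement, and -0.02 for oxidative phosphorylation. They were -0.02 for amyloid precursor protein processing and 0.15 for TGF-beta signalling and transcription factors. Intervals of the 81 named ratios reached a median of 0.05 to either side.

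The 5xFAD comparisons at P120 asked how microglia-like cells of libraries labelled 5xFAD differed, once among libraries without tamoxifen and once among those with it. DAM genes were far higher with 5xFAD in both. Cst7, which encodes cystatin F and marks stage 2, was at 1110 against 9.97 CPM without tamoxifen and 889.5 against 12.9 CPM with it. The growth factor gene Igf1 was at 305 against 6.17 and 204 against 3.18 CPM, Fabp5 at 356 against 9.38 and 207 against 7.92, and Baiap2l2 at 108 against 0.454 and 65.3 against 0.339. Lpl was at 641 against 25.1 and 344 against 17.9 CPM, Spp1 at 449 against 18.7 and 168 against 6.25, and Apoe, already abundant, at 28260 against 4516 and 16670 against 5287. Without tamoxifen the highest relative log2 ratios also included 5.99 for Gpnmb, 5.41 for Dkk2, 5.31 for Ch25h, 5.31 for Wfdc17, 5.21 for Etl4 and 5.15 for H2-Aa. With tamoxifen they included 4.62 for Etl4, 4.43 for Fabp3, 4.08 for Wfdc17 and 3.86 for Axl, Axl being a receptor tyrosine kinase for dying cells.

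Genes lower with 5xFAD at P120 included Serpinf1, a secreted serpin, at 51.4 against 375 CPM without and 102 against 349 with tamoxifen, and the adaptor gene Bank1 at 11.6 against 83.0 and 23.3 against 82.3. The transglutaminase gene Tgm2 was at 12.8 against 78.0 and 23.2 against 80.5, the tetraspanin gene Tspan18 at 14.0 against 91.3 and 24.4 against 80.5, and Siglece, an inhibitory receptor for sialic acids, at 8.17 against 50.3 and 16.6 against 48.9. Without tamoxifen the remaining lowest ratios were -2.08 for Slco4a1, -2.002 for Hlf, -1.95 for Camk2n1, -1.90 for Ggta1 and -1.88 for Actn1, and with tamoxifen -1.25 for Camk2n1, -1.16 for Naalad2, -1.14 for Klf7, -1.13 for Prkca and -1.10 for Dusp27. Without tamoxifen, 432 of 6182 measured genes were at least 1.5-fold higher and 2442 lower in CPM, 984 and 413 relative to the median, and 1047 higher and 367 lower with TMM scaling. With tamoxifen, 362 of 6186 were higher and 1330 lower in CPM, 738 and 204 relative to the median, and 745 higher and 202 lower with TMM scaling.

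All 10 stage 1 genes were at least 1.5-fold higher relative to the median in both 5xFAD comparisons, with list medians of 1.78 (95% interval 1.77 to 1.79) without and 1.35 (95% interval 1.34 to 1.36) with tamoxifen. So were all 21 and 20 measured stage 2 genes, at 2.56 (95% interval 2.52 to 2.58) and 1.86 (95% interval 1.83 to 1.87), while in CPM 19 of the 20 with tamoxifen passed. Homeostatic genes lay at -0.51 (95% interval -0.54 to -0.51) and -0.26 (95% interval -0.27 to -0.25), with 11 and 6 of 24 at least 1.5-fold lower relative to the median and 19 and 12 in CPM. Without tamoxifen 1 was at least 1.5-fold higher, Cx3cr1 at 3057 against 1823 CPM, a gene that lay at 1855 against 1812 with it. Crybb1 (-1.27 and -1.08), Tmem119 (-1.20 and -0.72) and the transcription factor gene Sall1 (-1.02 and -0.71) were the lowest. MHC class II lay at 4.40 (95% interval 4.30 to 4.48) and 2.16 (95% interval 2.09 to 2.23), with Cd74 at 774 against 40.8 and 338 against 57.5 CPM. Over all barcodes the MHC class II medians were 0.57 and 0.02. H2-Eb1 had log2 ratios of -0.39 and -0.79 there, not centred, where the medians of all genes were -0.46 and -0.31. Thus H2-Eb1 lay below the median of all genes only with tamoxifen. With the unnamed clusters nearest microglia added, an alternative chosen after seeing the data, the MHC class II medians were 0.71 and 0.06. H2-Eb1 lay at -0.28 and -0.86, also not centred, with the medians of all genes at -0.47 and -0.34. The interferon list lay at 2.66 without and 1.92 with tamoxifen, with Ifi27l2a at 651 against 38.5 and 538 against 48.1 CPM and Ifitm3 at 274 against 20.2 and 216 against 23.4. MHC class I lay at 1.51 and 0.95, with H2-D1 at 2.70 and 1.98. The tamoxifen comparison without 5xFAD measured 16 stage 2, 8 interferon and 3 MHC class II genes, against at least 20, 12 and 6 here. Part of these counts and medians thus follows from the rule for measured genes.

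Cytokines and chemokines lay at 1.5005 without and 1.41 with tamoxifen, where Ccl4 was at 1434 against 214 and 1421 against 159 CPM, Ccl3 at 913 against 136 and 944 against 128, and Il1b at 188 against 28.9 and 117 against 22.5. Glycolysis genes lay at 1.37 without and 1.16 with tamoxifen, among them Pgk1 (1.80 and 1.56), Tpi1 and Gapdh. Nuclear oxidative phosphorylation genes lay at 1.09 without and 0.91 with tamoxifen and mitochondrially encoded genes at 0.76 without and 0.54 with tamoxifen. Lipid transport and sterol genes lay at 0.95 without and 0.78 with tamoxifen, lysosome genes at 0.79 without and 0.62 with tamoxifen with Cd63 at 2.02 and 1.58, and phagocytosis receptors and complement at 0.61 without and 0.37 with tamoxifen with Axl at 4.53 and 3.86. The immediate early and stress list lay at 0.88 without and 0.56 with tamoxifen, with Atf3 at 2.39 and 2.59. Amyloid precursor protein processing lay at 0.26 without and 0.21 with tamoxifen, where Aplp2 was higher (1.86 and 1.43) and Notch1 lower (-0.59 and -0.71). Proliferation lay at 0.65 without and 0.92 with tamoxifen, and TGF-beta signalling and transcription factors at -0.05 without and -0.15 with tamoxifen with Maf at -0.90 and -0.64. Intervals of the named ratios reached medians of 0.063 and 0.058 to either side.

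The 5xFAD comparison at P420 asked the same at an older age in Bace1-fl/fl mice. These libraries differed in what the filters removed: without 5xFAD 954 of 8287 barcodes had fewer than 500 detected genes and 1218 more than 10% mitochondrial UMIs, against 250 and 467 of 8094 with it. In falling order of ratio, the apolipoprotein gene Apoc4 was at 216 against 0.319 CPM, Gpnmb at 993 against 5.14 CPM, Dkk2 at 114 against 0.461 CPM and Igf1 at 584 against 6.49 CPM. Then came Mamdc2 (relative log2 ratio 6.61), the proton pump subunit gene Atp6v0d2 at 85.5 against 0.248 CPM, Hpse, which encodes heparanase, at 106 against 1.03 CPM, Baiap2l2 (5.88), Lgi2 (5.74) and Fabp5 at 1132 against 27.9 CPM. Apoe reached 48960 CPM with 5xFAD against 3065 without. Eid1, an inhibitor of differentiation, had 1641 UMIs (58.2 CPM) without 5xFAD and 0 with it, where 3 UMIs would be 0.0427 CPM, and so was at least 1363-fold lower. Its absence did not go with 5xFAD at P120, where it had 0 UMIs in 3 of the 4 libraries, both without 5xFAD among them, and 7.43 CPM in the 5xFAD library without tamoxifen. Lrba was at 8.56 against 232 CPM and Ets1 at 3.19 against 85.4 CPM at P420. Both were low in the 4 P120 libraries with and without 5xFAD (Lrba from 8.76 to 23.02, Ets1 from 1.52 to 3.84 CPM) and in wild type at P75, and high in the knockout library. Across the ages these 3 genes did not follow 5xFAD. Relative log2 ratios were -3.35 for Pde2a, -3.26 for Gp9, -3.09 for Bank1, -2.80 for Fam110a, -2.75 for Ggta1, -2.53 for Rtn1 and -2.51 for Ggt5. Of 5840 measured genes, 401 were at least 1.5-fold higher and 1985 lower in CPM, 856 and 602 relative to the median, and 996 higher and 484 lower with TMM scaling.

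Stage 1 genes lay at 1.40 (95% interval 1.39 to 1.41) at P420 and stage 2 genes at 2.02 (95% interval 1.996 to 2.04), and each measured member (10 and 21) was at least 1.5-fold higher relative to the median, and 9 and 19 were in CPM. Cst7 was at 2115 against 90.5 CPM, Spp1 at 4428 against 387 CPM and the integrin gene Itgax at 277 against 29.0 CPM. Homeostatic genes lay at -0.81 (95% interval -0.82 to -0.79), with 14 of 24 at least 1.5-fold lower relative to the median and 20 in CPM, among them Selplg (-1.66), Tmem119 (-1.48), the fructose transporter gene Slc2a5 (-1.40) and Sall1 (-1.39). MHC class II lay at 2.62 (95% interval 2.57 to 2.66), 4 of 6 genes at least 1.5-fold higher and 1 lower, with H2-Aa at 155 against 18.8 CPM. Its median was -0.76 over all barcodes, where H2-Aa was at -1.19, Cd74 at -0.72 and H2-Eb1 at -1.70. These single gene ratios were not centred, and the median of all genes there was -0.37. Lipid transport and sterol genes lay at 1.11, glycolysis at 1.03, oxidative phosphorylation at 0.85, mitochondrially encoded genes at 0.67 (but 0.17 over all barcodes) and lysosome genes at 0.72 with Cd63 at 2.02. MHC class I lay at 0.79 and the interferon list at 0.54, where Ifi27l2a was at 338 against 122 CPM. Percentiles among random lists of matched expression were 93.0 for lysosome, 74.0 for mitochondrially encoded genes and 96.9 for MHC class I. These lists were thus not set apart from random ones. The lipid transport and sterol, glycolysis, oxidative phosphorylation and interferon lists were at least at 99.795.

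Cytokines and chemokines lay at -0.15 at P420, with Ccl9 (-1.89), Ccl2 (-1.65) and Il1a (-1.01) lower with 5xFAD. Relative to the median, these 3 of 11 members were at least 1.5-fold lower and 5 higher, but in CPM 5 were lower and 1 higher, so the balance turned with the scaling. Those higher relative to the median included Ccl4 at 1412 against 915 CPM and Ccl3 at 1039 against 701, both chosen after their values were seen. The immediate early and stress list lay at 0.38 with Hspa1a at -1.64 and Ier3 at 1.81. Medians were 0.25 for phagocytosis receptors and complement, 0.22 for amyloid precursor protein processing (but -0.32 over all barcodes), 0.14 for proliferation and 0.00 for TGF-beta signalling and transcription factors. In that last list Bhlhe40, a repressor linked to lipid handling in macrophages, was at 44.7 against 3.19 CPM and Maf at 246 against 729 CPM. The astrocyte-like share was 4.10% in the 5xFAD library against 0.255% in the other, but 0% in both at resolution 0.5, where no cluster was named so. Intervals of the 86 named ratios reached a median of 0.064 to either side.

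**Figure D2:**
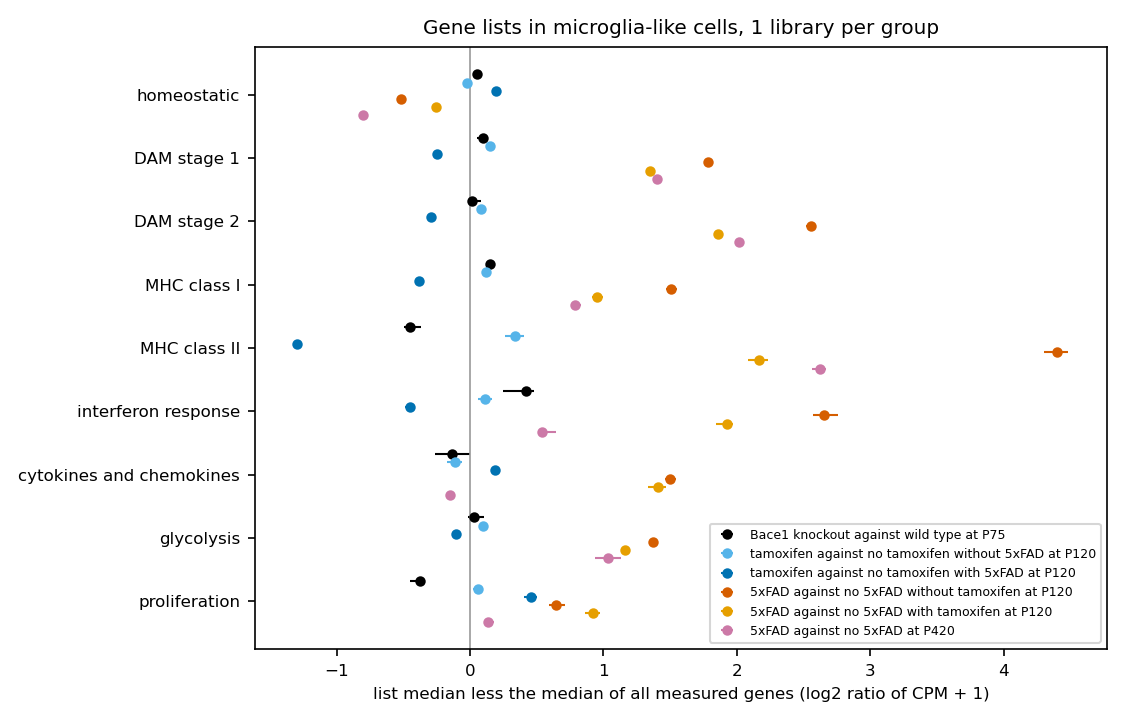
Relative median log2 ratio of 9 gene lists in the 6 comparisons, with 95% intervals from Poisson draws. Stage 2 medians lie at 2.56, 1.86 and 2.02 in the 5xFAD comparisons, and the MHC class II median for tamoxifen lies at 0.34 without and -1.30 with 5xFAD, over 3 and 6 measured genes.

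Cells in the high range of the stage 2 score were counted after every microglia-like cell had been thinned to 1000 UMIs. The score was the percent of a cell's UMIs from stage 2 genes, and the limit was the 95th percentile of the reference library of the same age, 1.5% of UMIs at P75 and P120 and 2.0% at P420. With 5xFAD at P120, 59.5% (58.2 to 60.8) of cells lay above the limit without tamoxifen and 47.0% (45.4 to 48.7) with it, and at P420 60.6% (59.3 to 61.8) did. Without 5xFAD the shares were 4.89% without tamoxifen, which set the limit, and 6.02% (5.26 to 6.86) with it, and 4.45% in the P420 reference. In the knockout library the share was 5.60% (4.99 to 6.25) against 3.53% in the wild type reference, but with stage 1 and stage 2 genes scored together it was 4.36% against 4.54%. Without thinning the shares were 5.01% and 7.38% at P75, 5.00%, 5.72%, 73.0% and 59.3% at P120 in the order above, and 5.01% and 69.5% at P420. Thinning left out 8, 0, 12, 9, 15, 7, 12 and 17 cells in that order, and 271, 397, 221, 262, 771, 501, 131 and 628 cells lay within 1 UMI of the limit.

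**Figure D3:**
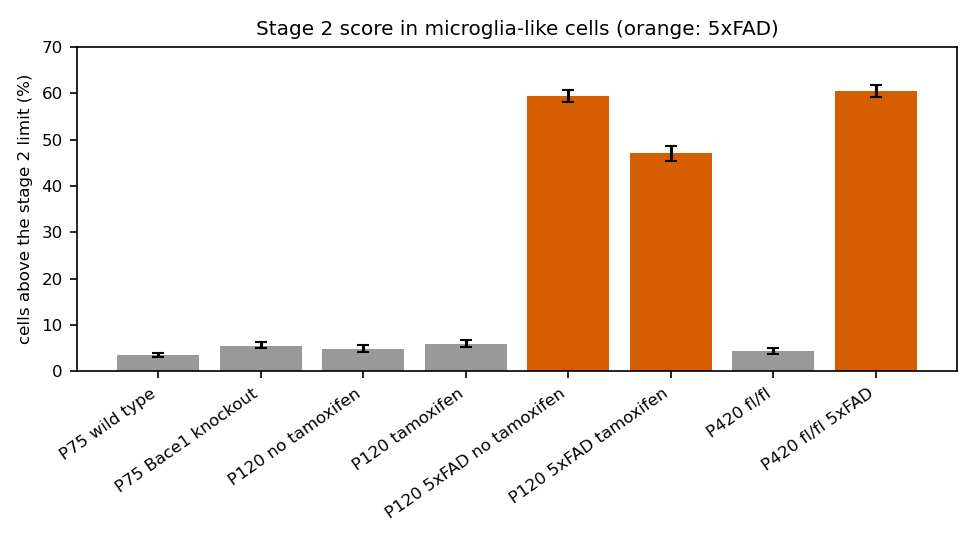
Percent of microglia-like cells above the stage 2 limit in the 8 libraries after thinning to 1000 UMIs per cell, 1 bar per library, with exact 95% binomial intervals and 5xFAD libraries in orange. The 5xFAD libraries lie at 59.5%, 47.0% and 60.6%, and the others between 3.53% and 6.02%.

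Shares of microglia-like cells with at least 1 UMI were also taken after thinning. Cst7 was found in 43.8% of cells with 5xFAD at P120 without tamoxifen, 34.0% with it and 56.7% at P420, against 0.699%, 0.682% and 4.59% without 5xFAD. In endothelial cell-like cells, which should lack it, the 5xFAD shares were 4.35%, 3.59% and 10.1%. Without thinning Cst7 was found in 78.6%, 68.6% and 85.1% of the 5xFAD cells. Gpnmb was found in 4.68%, 1.58% and 27.4% of 5xFAD cells and in 0 of the endothelial cell-like cells. Cd74 was found in 15.2% of wild type and 7.72% of knockout cells, against 11.5% (7.25 to 17.0) and 5.16% (1.70 to 11.6) in endothelial cell-like cells, and in 25.6% and 14.6% of P120 5xFAD cells without and with tamoxifen, against 2.17% and 1.80%. P2ry12, a purine receptor gene of resting microglia, was found in 97.2% and 95.7% of P120 cells, 71.1% and 78.7% with 5xFAD, and 87.6% and 53.9% at P420 without and with it. Apoe was found in 47.8% of knockout and 28.7% of P420 cells without 5xFAD, at or below the 55.7% and 57.6% of endothelial cell-like cells. In CPM it was higher than in those cells, at 1295 against 824 and 3065 against 1014. Median UMIs per microglia-like and endothelial cell-like cell were 2549.5 and 3072.5 in the wild type library, 2804 and 2688 in the knockout library, 8521 and 6366, 8075 and 6120, 10095 and 7462.5, and 11339 and 8382 at P120, and 6084.5 and 5870.5, and 9655 and 9060 at P420.

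Log2 ratios were also compared across genes between comparisons with no library in common, as a description, since genes are not independent replicates. The 5xFAD comparisons without and with tamoxifen had a Pearson r of 0.97 (Spearman 0.94, 6086 genes). Of the genes measured in both, 411 and 355 were at least 1.5-fold higher and 338 were shared, against 24.0 if the comparisons were independent. For lower genes, 1285 were shared against 518. These counts are in CPM, where the medians of all genes lay at -0.48 and -0.35, an offset that enters the shared lower genes. Relative to the median 413 and 204 genes were lower, and their overlap was not counted. With 5xFAD at P420 the r was 0.88 (Spearman 0.87, 5422 genes) for the comparison without tamoxifen and 0.84 (Spearman 0.84, 5437 genes) for the one with it. Tamoxifen with 5xFAD gave an r of -0.61 (Spearman -0.47, 5232 genes) with 5xFAD at P420, and tamoxifen without 5xFAD one of 0.32 (Spearman 0.37, 5384 genes). The tamoxifen comparisons without and with 5xFAD had an r of 0.04 (Spearman 0.05, 5484 genes), which was -0.01 among genes of at least 50 CPM. The knockout comparison had r values of -0.10 and -0.0004 with tamoxifen without and with 5xFAD, -0.08 and -0.09 with 5xFAD at P120, and -0.19 with 5xFAD at P420.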

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

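Of the tests below, those of depth and of the stage 1 and homeostatic lists were chosen after the result was seen, while those of the MHC class II list and of border macrophage RNA were set before. For 8 lists the relative median of the tamoxifen comparison had opposite signs with and without 5xFAD and lay beyond the central 95% of matched random lists both times. With 1 library per group these differences were not tested. Medians with against without 5xFAD were -1.30 against 0.34 (difference -1.64) for MHC class II, -0.45 against 0.12 (difference -0.57) for interferon response, -0.38 against 0.12 (difference -0.50) for MHC class I and -0.24 against 0.15 (difference -0.40) for stage 1. They were 0.19 against -0.12 (difference 0.31) for cytokines and chemokines, 0.20 against -0.02 (difference 0.22) for homeostatic genes, -0.10 against 0.10 (difference -0.20) for glycolysis and 0.15 against -0.04 (difference 0.19) for TGF-beta signalling and transcription factors. Measured genes numbered 6 against 3 for MHC class II, 17 against 8 for interferon response, 9 against 8 for MHC class I and 12 against 9 for cytokines and chemokines, and were equal in number for the rest. Over the genes measured in both comparisons the medians of these 4 were -0.07 against 0.34, -0.43 against 0.12, -0.34 against 0.12 and 0.10 against -0.12, so most of the MHC class II difference came from genes not measured without 5xFAD. Under each of the 12 alternatives 6 of these lists kept opposite signs. MHC class II did not over all barcodes (-0.72 against -0.09), and without 5xFAD it lay at 0.01 with the unnamed clusters nearest microglia added. Cytokines and chemokines did not over all barcodes (0.08 against 0.01).

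With 5xFAD the tamoxifen library had lower MHC class II and stage 1 medians and a higher homeostatic median. In cells matched on bins of the stage 2 score, 87.6% (87.3 to 88.0) of the MHC class II median remained. The MHC class II median was not centred on all genes (-1.22 to -1.07), and the relative one went from -1.30 to -1.12, or 86.7%. Of the stage 2 median itself 56.9% (53.6 to 62.5) also remained, so the matching did not make the stage 2 genes even. It therefore cannot exclude fewer cells in the high stage 2 range as a source of the MHC class II part. RNA of border macrophages is argued against by its markers, which lay higher with tamoxifen, at a median log2 ratio of 0.587 (0.484 to 0.709; 9 of 10 higher). Unequal depth is argued against by cells matched on UMIs per cell in 5 bins, a test that replaced an earlier one with thinned cells. There 106.5% (106.2 to 106.9), 116.2% (114.0 to 116.8) and 112.8% (107.0 to 117.0) of the 3 relative medians remained, while the ratio of mean UMIs per cell went from 1.28 to 1.09. After matching on the stage 2 score 55.3% (53.5 to 58.4) of the stage 1 median and 71.8% (68.9 to 75.6) of the homeostatic median remained, again not centred (-0.17 to -0.09 and 0.28 to 0.20). The relative medians went from -0.24 to -0.15, or 60.4%, and from 0.20 to 0.14, or 71.8%, so a lower share of high-scoring cells may account for part of either. Bace1 deletion, tamoxifen itself, unlike numbers of intact Cx3cr1 copies and differences between animals also stay open, untested, because each goes with the library.

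These clusters outside the compared class held, with 5xFAD, at least 3 times the share of the control library of the same treatment, with intervals apart. Only higher shares with 5xFAD were looked for. At P120 an unnamed cluster with Gfap and other astrocyte transcripts among its leading genes, shallow in UMIs, held 3.99% and 3.85% of the 5xFAD cells without and with tamoxifen, against 0.434% and 0.300% without 5xFAD. At P420 the astrocyte-like cluster held 4.10% of 5xFAD cells against 0.255%, and the T cell-like cluster 1.60% against 0.447%. An unnamed P420 cluster with Plac8, Itgal and Ace among its leading genes held 1.56% against 0.287%. A further unnamed P420 cluster, with Lgals3, Apoe and Spp1 among them, held 1.40% against 0.335%. Other unnamed clusters went the other way. Among them, P420 clusters held 0.587% with against 16.6% without 5xFAD, and 0.630% against 3.32%. A P120 cluster held 1.19% and 1.21% with 5xFAD, without and with tamoxifen, against 8.76% and 9.64% without 5xFAD. Genes of unnamed clusters were chosen after their values were seen.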

How the results depend on the processing

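Alternatives fixed before the data were examined and 3 chosen after seeing them (unnamed clusters nearest microglia added, and microglia-like cells taken from the clusterings at resolutions 0.5 and 1.5) were run 1 at a time. No analysis paired by replicate number was made, because each group had 1 library and the only number, 1, was given in accession order and joins no libraries. A fit of 5xFAD blocked by its 3 pairs was possible and was left out, as stated above. No library could be left out of a comparison of 1 library with 1. Values without a test counted as moved where they left their counting interval, and counts where they moved by over 1.5 times. Of single gene ratios, 4106 stayed, 1664 moved and 14 turned direction. Of list medians 952 stayed, 326 moved and 6 turned. Turning was counted only for genes at least 1.5-fold apart and lists outside the central 95% of random lists in the main setting. Gene ratios in this part were not centred on the median of all genes, while list medians were. The sign also changed in 30 other gene ratios, at most 0.48 from 0 in the main setting, and in 22 other list medians, at most 0.22 from 0. Gene counts stayed in 50 instances and moved in 28, shares above the stage 2 limit in 22 and 34, and cell type shares in 98 and 42. Counts of lists outside the central 95% of random lists stayed in 70 instances and moved in 2, and correlations in 4 and 7. Requiring 1000 detected genes per cell moved none of the counts, homeostatic, stage 1, stage 2 or MHC class II medians, or shares printed here. Depth limits genes of low counts most: at P75 the median barcode held 2616 and 2903 UMIs, and the lowest 969 and 1835. Except where stated, the cause was not tested.

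All barcodes gave homeostatic medians of 0.10 for knockout, -0.053 for tamoxifen without 5xFAD, 0.093 for tamoxifen with 5xFAD, -0.47 for 5xFAD without tamoxifen, -0.29 for 5xFAD with tamoxifen and -0.71 for 5xFAD at P420. The stage 1 medians there were -0.33 for tamoxifen with 5xFAD, 1.66 for 5xFAD without tamoxifen, 1.27 for 5xFAD with tamoxifen and 1.34 for 5xFAD at P420. For the stage 2 list they were, in that order, -0.38, 2.20, 1.73 and 1.85. MHC class II genes gave, in the order of the homeostatic medians, -0.65, -0.091, -0.72, 0.57, 0.020 and -0.76. Single genes turned direction with 5xFAD. H2-Eb1 lay at -0.39 without tamoxifen, -0.79 with tamoxifen and -1.70 at P420. H2-Aa lay at -0.46 with tamoxifen and -1.19 at P420, and H2-Ab1 at -0.41 and -1.07 in that order. At P420 Cd74 lay at -0.72 and Ifitm3 at -0.18. The medians of all genes there were -0.46 for 5xFAD without tamoxifen, -0.31 with tamoxifen and -0.37 at P420. H2-Eb1 for 5xFAD without tamoxifen and Ifitm3 at P420 thus lay above these medians. Cytokine and chemokine medians turned to 0.065 for knockout and 0.008 for tamoxifen without 5xFAD. Genes 1.5-fold apart numbered 84 (74 higher) for tamoxifen without 5xFAD and 176 (134 higher) for tamoxifen with 5xFAD. For knockout, 6 lists lay outside the central 95% of random lists.

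Adding the unnamed clusters gave homeostatic medians of 0.18 for tamoxifen with 5xFAD, -0.50 for 5xFAD without tamoxifen, -0.27 for 5xFAD with tamoxifen and -0.85 for 5xFAD at P420. The stage 1 medians there were -0.26 for tamoxifen with 5xFAD, 1.76 for 5xFAD without tamoxifen, 1.33 for 5xFAD with tamoxifen and 1.39 for 5xFAD at P420. For the stage 2 list they were 2.41 for 5xFAD without tamoxifen, 1.77 for 5xFAD with tamoxifen and 1.92 for 5xFAD at P420. MHC class II genes gave -0.58 for knockout, 0.014 for tamoxifen without 5xFAD, -0.75 for tamoxifen with 5xFAD, 0.71 for 5xFAD without tamoxifen, 0.055 for 5xFAD with tamoxifen and 2.46 for 5xFAD at P420. For 5xFAD, H2-Eb1 turned to -0.28 without and -0.86 with tamoxifen, and H2-Aa to -0.49 and H2-Ab1 to -0.41 with tamoxifen. The medians of all genes were then -0.47 without and -0.34 with tamoxifen, so H2-Eb1 without tamoxifen lay above its median. The count for tamoxifen without 5xFAD was 15 (10 higher). Microglia-like cells of the coarser clustering gave homeostatic medians of 0.12 for knockout. The stage 1 medians there were -0.040 for knockout and 1.38 for 5xFAD at P420. For the stage 2 list they were -0.055 for knockout and 1.95 for 5xFAD at P420. MHC class II genes gave -0.80 for knockout and 2.46 for 5xFAD at P420. Those of the finer clustering gave homeostatic medians of 0.078 for knockout and -0.83 for 5xFAD at P420. With the finer clustering the stage 1 medians there were 0.016 for knockout and 1.51 for 5xFAD at P420. Its stage 2 medians were -0.021 for knockout and 2.10 for 5xFAD at P420. Its MHC class II medians were -0.69 for knockout, 4.60 for 5xFAD without tamoxifen and 2.75 for 5xFAD at P420.

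Equal weight per cell gave homeostatic medians of 0.038 for knockout, 0.24 for tamoxifen with 5xFAD, -0.49 for 5xFAD without tamoxifen, -0.20 for 5xFAD with tamoxifen and -0.78 for 5xFAD at P420. The stage 1 medians there were -0.28 for tamoxifen with 5xFAD, 1.66 for 5xFAD without tamoxifen, 1.22 for 5xFAD with tamoxifen and 1.43 for 5xFAD at P420. For the stage 2 list they were 0.088 for knockout, -0.32 for tamoxifen with 5xFAD, 2.48 for 5xFAD without tamoxifen and 1.59 for 5xFAD with tamoxifen. MHC class II genes gave -0.76 for knockout, 0.25 for tamoxifen without 5xFAD, -1.47 for tamoxifen with 5xFAD, 2.30 for 5xFAD with tamoxifen and 2.37 for 5xFAD at P420. Spp1 turned to -0.064 for knockout, and the immediate early and stress list to -0.008 for tamoxifen with 5xFAD. Keeping called doublets gave stage 1 medians of 1.77 for 5xFAD without tamoxifen and 1.44 for 5xFAD at P420. With doublets the stage 2 medians there were 2.05 for 5xFAD at P420. MHC class II medians with doublets were -1.27 for tamoxifen with 5xFAD and 2.49 for 5xFAD at P420.

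Without mitochondrial, ribosomal and immediate early genes, the homeostatic medians were -0.50 for 5xFAD without tamoxifen, -0.24 for 5xFAD with tamoxifen and -0.79 for 5xFAD at P420. Stage 1 medians were then 1.80 for 5xFAD without tamoxifen, 1.36 for 5xFAD with tamoxifen and 1.42 for 5xFAD at P420, and the stage 2 median 2.04 for 5xFAD at P420. The count was 1094 (430 higher) for 5xFAD with tamoxifen, and 6 lists lay outside the central 95% for knockout. A pseudocount of 0.1 gave homeostatic medians of -0.51 for 5xFAD without tamoxifen, stage 1 medians of 1.79 for 5xFAD without tamoxifen, 1.36 for 5xFAD with tamoxifen and 1.41 for 5xFAD at P420 and an MHC class II median of 4.54 for 5xFAD without tamoxifen. A pseudocount of 5 drew ratios of low counts towards 0 by construction. It gave homeostatic medians of -0.56 for 5xFAD without tamoxifen, -0.29 for 5xFAD with tamoxifen and -0.84 for 5xFAD at P420. The stage 1 medians there were -0.24 for tamoxifen with 5xFAD, 1.74 for 5xFAD without tamoxifen, 1.32 for 5xFAD with tamoxifen and 1.36 for 5xFAD at P420. For the stage 2 list they were 2.49 for 5xFAD without tamoxifen, 1.81 for 5xFAD with tamoxifen and 1.98 for 5xFAD at P420. MHC class II genes gave, in the order of the stage 1 medians, -1.27, 3.90, 1.91 and 2.47.

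A 2-fold threshold left fewer genes by construction: 41 (21 higher) for knockout, 2 (1 higher) for tamoxifen without 5xFAD, 23 (8 higher) for tamoxifen with 5xFAD, 744 (214 higher) for 5xFAD without tamoxifen, 281 (146 higher) for 5xFAD with tamoxifen and 787 (183 higher) for 5xFAD at P420. Without a CPM minimum more genes entered. In the same order there were 1044 (307 higher), 76 (49 higher), 351 (219 higher), 5586 (978 higher), 3385 (905 higher) and 5285 (1012 higher). A minimum of 50 CPM left, in that order, 81 (37 higher), 3 (2 higher), 42 (21 higher), 1522 (301 higher), 965 (252 higher) and 1158 (254 higher). TMM factors, which scale all counts of a library alike, gave 1414 (1047 higher) for 5xFAD without tamoxifen, 947 (745 higher) for 5xFAD with tamoxifen and 1480 (996 higher) for 5xFAD at P420. Median-of-ratios factors gave, in the order of the TMM counts, 1442 (1130 higher), 981 (815 higher) and 1486 (1016 higher).

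Correlations across genes of at least 50 CPM were -0.0427 between knockout and tamoxifen with 5xFAD, -0.0096 between tamoxifen without 5xFAD and tamoxifen with 5xFAD and 0.38 between tamoxifen without 5xFAD and 5xFAD at P420. They were also -0.65 between tamoxifen with 5xFAD and 5xFAD at P420, 0.97 between 5xFAD without tamoxifen and 5xFAD with tamoxifen, 0.90 between 5xFAD without tamoxifen and 5xFAD at P420 and 0.86 between 5xFAD with tamoxifen and 5xFAD at P420.

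With the limit at the 90th percentile the stage 2 shares were 7.98% in P120 tamoxifen, 64.7% in P120 5xFAD, 51.9% in P120 5xFAD tamoxifen, 11.6% in knockout and 70.8% in P420 5xFAD, and at the 99th 0.739% in P120 tamoxifen, 36.3% in P120 5xFAD, 28.1% in P120 5xFAD tamoxifen, 1.21% in knockout and 31.2% in P420 5xFAD. At the 99th percentile the P120 reference without tamoxifen lay at 0.826%, above the library with tamoxifen, the reverse of the main order. Unthinned they were 73.0% in P120 5xFAD, 59.3% in P120 5xFAD tamoxifen, 7.38% in knockout and 69.5% in P420 5xFAD. Thinning to 2000 UMIs gave 67.6% in P120 5xFAD, 54.0% in P120 5xFAD tamoxifen, 7.57% in knockout and 65.9% in P420 5xFAD. Stage 1 and stage 2 genes together gave 7.19% in P120 tamoxifen, 79.7% in P120 5xFAD, 60.4% in P120 5xFAD tamoxifen, 4.36% in knockout and 83.4% in P420 5xFAD. Leaving out the most abundant stage 2 member gave 7.89% in knockout.

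At resolution 0.5, microglia-like shares were 48.3% in wild type, 85.6% in knockout and 87.0% in P420 5xFAD, and unnamed shares 41.7% in wild type, 5.17% in knockout, 18.4% in P420 and 6.29% in P420 5xFAD. Border macrophage-like shares were 5.44% in P420 and 1.83% in P420 5xFAD, and pericyte or smooth muscle-like shares 1.06% in wild type and 2.14% in knockout. Astrocyte-like shares were 1.23% in wild type, 0.657% in knockout, 0% in P420 and 0% in P420 5xFAD. Neutrophil-like shares were 0% in the 4 P120 libraries. At resolution 1.5, microglia-like shares were 87.1% in P120 without tamoxifen, 81.5% in P120 tamoxifen, 91.5% in P120 5xFAD, 58.6% in wild type, 86.4% in knockout, 77.8% in P420 and 80.2% in P420 5xFAD. Unnamed shares were then, in that order, 6.72%, 8.61%, 5.64%, 32.3%, 6.17%, 10.4% and 9.51%. The monocyte-like share was 0.498% in wild type, and astrocyte-like and neutrophil-like shares were 0% in the 4 P120 libraries.

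Other list medians that moved by at least 0.2 are given here. Over all barcodes they were 0.14 for interferon response (knockout), -0.10 for mitochondrially encoded genes (knockout), 2.40 for interferon response (5xFAD without tamoxifen), 1.15 for cytokines and chemokines (5xFAD without tamoxifen), 1.72 for interferon response (5xFAD with tamoxifen), 1.19 for cytokines and chemokines (5xFAD with tamoxifen), 0.76 for lipid transport and sterol (5xFAD at P420), -0.32 for amyloid precursor protein processing (5xFAD at P420) and 0.17 for mitochondrially encoded genes (5xFAD at P420). With the coarser clustering they were -0.50 for immediate early genes (knockout) and -1.04 for proliferation (knockout). With the finer clustering they were -0.36 for immediate early genes (knockout) and -0.88 for proliferation (knockout). At equal weight per cell it was 1.70 for interferon response (5xFAD with tamoxifen). Without mitochondrial, ribosomal and immediate early genes they were 1.25 for cytokines and chemokines (5xFAD without tamoxifen) and 2.22 for interferon response (5xFAD with tamoxifen). With TMM or median-of-ratios factors it was 2.19 for interferon response (5xFAD with tamoxifen). With a pseudocount of 5 they were 2.36 for interferon response (5xFAD without tamoxifen) and 1.70 for interferon response (5xFAD with tamoxifen).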

Other observations

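All tests in this part but that of the Cx3cr1 ratio over score bins were chosen after the result was seen, and so were the genes named in this paragraph. Border macrophage-like cells, 145 and 236 at P120 without 5xFAD and 102 and 127 with it, had lower interferon response genes in both tamoxifen libraries. With counts also relative to the median of all genes, the relative median was -0.65 (9 of 18 at least 1.5-fold lower) without 5xFAD and -0.57 (8 of 19 at least 1.5-fold lower) with it. Counts of single genes were low. Cxcl10, an interferon-induced chemokine gene, had 9 against 86 UMIs (log2 ratio -3.63, 95% interval -5.00 to -2.84) with against without tamoxifen in the absence of 5xFAD and 4 against 35 UMIs (log2 ratio -3.57, 95% interval -5.82 to -2.38) in its presence. Log2 ratios of the antiviral genes Rsad2 and Ifit2 were -3.11 (-4.04 to -2.46) and -3.20 (-4.13 to -2.56) without 5xFAD, and -1.82 (-2.96 to -0.91) and -1.35 (-2.31 to -0.52) with it.

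With 5xFAD, stage 2 genes were higher in border macrophage-like cells too, at relative medians of 1.07 (12 of 19 at least 1.5-fold higher) without tamoxifen, 0.70 (9 of 17 at least 1.5-fold higher) with it and 0.70 (10 of 19 at least 1.5-fold higher) at P420. In that order the tetraspanin gene Cd9 had log2 ratios of 1.02 (0.76 to 1.29), 1.14 (0.98 to 1.298) and 1.72 (1.40 to 2.06), Fabp5 of 1.55 (0.83 to 2.39), 1.34 (0.73 to 2.05) and 2.52 (1.999 to 3.15), and Lpl of 3.61 (2.59 to 5.32), 3.74 (2.78 to 5.76) and 2.96 (1.92 to 4.77). Spp1 had 2.83 (1.86 to 4.29) without tamoxifen and 2.09 (1.56 to 2.72) at P420. These genes too were chosen after their values were seen, and RNA from microglia in the same droplets was not separated from these counts.

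Cx3cr1 lay higher in the P120 5xFAD library without tamoxifen than in the other P120 libraries. A lower activation of that library is argued against: the other homeostatic genes lay higher with tamoxifen, at a median log2 ratio of 0.276, 22 of 23 of them. Over 4 bins of the stage 2 score the ratio of Cx3cr1 without to with tamoxifen was at least 1.697 (1.679 to 1.716) and at most 1.826. A candidate explanation is thus a different number of intact Cx3cr1 copies, that is, a CreER genotype other than labelled, which was not read directly. The level alone does not tell the genotype, since the P420 5xFAD library, with no Cre label, lay at 1852 CPM, within the 1812 to 1855 of the other 3 P120 libraries. Eid1, chosen after its values were seen, was at 7.43 CPM in the P120 5xFAD library without tamoxifen and at 0 UMIs in those 3. The tamoxifen comparison with 5xFAD and the 5xFAD comparison without tamoxifen, which share that library, may thus also carry a difference of genotype. So may the 5xFAD comparison at P420, where Eid1 was at 58.2 CPM without 5xFAD and at 0 UMIs with it. An effect of tamoxifen or of Bace1 deletion under 5xFAD stays open, untested.

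Between knockout and wild type, 41 genes lay at least 2-fold apart at P75. Of the 39 genes in every feature table, 5.13% (0.63 to 17.32) had only the knockout value outside the range of the 6 libraries of the other ages, and 33.33% (19.09 to 50.22) only the wild type value. In 20 genes both values lay outside. Those 6 libraries also differ from the P75 pair in age and in sex-linked genes, which may move both values, so a knockout or a wild type library that stands apart stays open. Within 20 Mb of Bace1 lay 2.44% (0.06 to 12.86) against 1.92% of all measured genes, an interval too wide to decide on a chromosome segment carried along with the allele. Parts of the genome outside this 20 Mb window were not tested in this way. Lrba, Fcrls and Fcrl1, picked after their values were seen, lie between 86224680 and 87402934 on chromosome 3. Loss of Bace1 itself and differences between animals stay open, untested.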
